A study of Mus musculus with 2 samples.

How the data were processed

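Total RNA depleted of ribosomal RNA was sequenced from 2 cultures of G1E, an immortalized mouse line that the labels describe as an erythroid progenitor without Gata1. The labels number the cultures as biological replicates 1 and 2 and give no second condition, so both libraries form 1 group and no contrast between groups exists. Per the labels, 100 ng of RNA entered a ScriptSeq library preparation with a size range of 200 to 1000 nt. Random-primed total RNA keeps transcripts without a poly(A) tail, such as replication-dependent histone mRNAs and the small nuclear RNAs, and these take part of every value that is scaled to the library total.

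The authors deposited gene and transcript tables for each library, with 1 library per table and no pooling. Per the file headers, each table holds an expected count, a TPM, an FPKM, posterior means of these and an interval for the TPM. The deposited expected counts are estimated reads per gene or transcript: reads that fit several genes are divided among them, so the values need not be whole. In the deposited TPM values the estimated reads are divided by an effective length and scaled to the same fixed total in every library, and the deposited FPKM values divide by the same effective length and by the number of reads in the library. The transcript tables also hold a percent, the share of the gene's abundance in each transcript, per the file headers. The deposited read-me texts name the mm10 assembly and release M4 of the GENCODE annotation. Signal of the plus and minus strands is named there too, but the strand used for counting is not given in the sources used here, so genes that overlap on opposite strands are uncertain. The aligner, the quantifier and their versions are not given in the sources used here, and neither is the level of the deposited TPM interval, which is quoted as the authors' interval.

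Gene tables had 69691 rows: 43346 genes, 97 spike-in sequences (96 ERCC and 1 phiX) and 26248 rows with numeric names. Spike-in rows held 0 counts in both libraries. Rows with numeric names held 20 and 37.61 expected counts in replicates 1 and 2, and these rows stayed out of library sizes and tests. Gene symbols, gene types and coordinates came from GENCODE release M21, a later annotation on the same GRCm38 (mm10) assembly, matched on the Ensembl gene identifier without its version. Of the 43346 genes, 42462 had a match and 884 did not. These unmatched genes held 0.174% and 0.170% of the counts in replicates 1 and 2.

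Expected counts on genes summed to 58094631 in replicate 1 and 55274368 in replicate 2. The effective lengths correspond to mean fragments of 213.2 and 192.5 nt. For 3808 and 2497 genes the effective length was 0, so the 555 and 1489 counts on them have no TPM. A count of 0 allows up to 3 counts, which is 0.0516 CPM (counts scaled by library depth) in replicate 1 and 0.0543 in replicate 2. Such limits cover counting error only, since the reads carry no molecular identifiers. A gene counted as detected at a TPM of at least 1 in both libraries. Levels are given as mean TPM ± SD with n = 2. For a list, the centre is the median of its members' mean TPM, and the SD is that of the 2 libraries' list medians. Log2 values of TPM use a pseudocount of 1, which understates the ratios of genes near 0. TPM differences by gene length and of snRNA, snoRNA and scaRNA genes use none. Those are relative to a median of -0.138 among detected genes with at least 200 counts over both libraries. Replicate error was the pooled SD of log2(TPM + 1) over detected genes, taken from the squared differences between the libraries, overall and in bins of mean TPM (1 to 10, 10 to 100, 100 to 1000, above 1000). As small RNAs took most of the TPM, TPM was also rescaled so that protein-coding genes outside the mitochondrial genome alone fill that total. A gene was marked as sharing reads where the posterior SD of its count exceeded 0.05 of its posterior mean in either library.

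The biological coefficient of variation came from the common dispersion of edgeR 4.0.16 on expected counts rounded to whole numbers, with TMM factors, an intercept-only design and at least 10 counts in both libraries; DESeq2 1.42.0 in R 4.3.3 gave alternative size factors and dispersions. The libraries were compared gene by gene with a two-sided exact binomial test of the rounded expected counts given TMM-scaled library sizes, with Benjamini-Hochberg adjustment at 0.05 over genes with at least 10 counts over both libraries, and a minimum of 2-fold. This test compares 2 libraries, not conditions, and knows counting error only. With 2 libraries the smallest two-sided exact p of a sign test is 0.5, so no statement on a single gene within the line rests on a p-value across libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did all other steps.

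A total of 21 gene lists and 15 gene pairs were fixed before the data were examined; the lists hold 466 different genes with values. Each list's median of mean TPM was placed among 10000 random lists of the same size drawn from protein-coding genes outside the mitochondrial genome. Each list's median log2 difference between libraries was placed among 10000 random lists matched on mean expression in 20 bins, and a list outside the middle 95% is called shifted. A pair was called different where both libraries gave the same sign and the smaller log2 ratio exceeded 3 times the square root of 2 times the pooled SD in the expression bin of the lower gene. Leading transcripts were described for named genes with at least 2 transcripts and at least 100 expected counts in both libraries.

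The rule for named genes was also fixed in advance. It takes Gata1 and both genes of every pair; the 3 highest and the lowest member of each list by mean TPM, and every detected member where 3 or fewer are detected; the 10 protein-coding nuclear genes and the 5 genes of any type with the highest mean TPM; and the 5 protein-coding genes with the largest difference between libraries in each direction among those past the test with at least 100 counts in a library. The rule named 125 genes, 17 of them with a shared-read mark, and any other gene in the text is said to have been chosen after its values were seen. Ahsp and Snhg1, which the lists include, have no values under these symbols and were not analysed here.

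The dispersion, binomial and list steps were tested on simulated data. For simulated between-library coefficients of variation of 0.1 and 0.2, edgeR returned 0.0989 over 14216 genes and 0.198 over 14113 genes. The binomial test was run on counts simulated with counting error only (Poisson). Among 200 genes changed 3-fold, with 18477 genes tested, 152 (76.0%) were called past 2-fold with 1 false call. Among 200 genes changed 1.5-fold, 101 (50.5%) passed at any fold, with 2 false calls over 18442 tested genes. Unchanged genes had no other variation there, so these false calls do not give the error rate in the real libraries. Of 200 unchanged random lists of 20 genes from the 18409 tested genes, 4.0% fell outside the middle 95%, and of 200 lists shifted by a log2 of 0.5, 99.0% did. Random lists ranked among random lists of the same genes check the procedure only. The 4.0% does not apply to lists whose members move together, as through a shared length. Alternatives covered the detection threshold, the unit (posterior mean TPM, rescaled TPM, FPKM, counts), the pseudocount, filters on low counts, the normalization, the fold minimum and leaving out each replicate. Random lists matched on gene length as well as expression were added after the data had been seen.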

Results

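The series profiles total RNA of G1E, an immortalized line of mouse erythroid progenitors labelled as lacking Gata1, the transcription factor that drives erythroid maturation. The line was derived from gene-targeted embryonic stem cells and is used to study what GATA1 does when it is given back. There was 1 group with 2 biological replicates, with 58094631 and 55274368 expected counts on genes. The labels name no treatment and no second line, so the comparisons the design allows are between genes within the line and between its 2 libraries. Values of genes are mean TPM ± SD of the 2 libraries (n = 2). Values of lists are the median of the members' mean TPM ± SD of the 2 libraries' list medians.

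The targeted gene came first. Gata1 (ENSMUSG00000031162.10, chromosome X, 7959260 to 7978071 on the minus strand, mm10) held 1862 and 1922 expected counts in replicates 1 and 2. Its level was 7.10 ± 0.049 TPM, or 40.6 ± 2.04 when TPM was rescaled to protein-coding nuclear transcripts. The authors' interval for its TPM ran from 6.66 to 7.45 in replicate 1 and from 6.72 to 7.49 in replicate 2. At this gene 3 counts are worth 0.011 TPM, so the RNA lay far above the limit of detection in both libraries of the line labelled Gata1-. Which part of the gene was altered is not in the labels, and a gene total neither checks nor contradicts the label.

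The regulators of early haematopoietic and erythroid cells were expressed as a group. Of 30 measured, 28 were detected in both libraries, with a list median of 8.51 ± 0.626 TPM, at percentile 100 of random lists of the same size. Myb, a factor of immature haematopoietic cells, led at 45.1 ± 3.03 TPM, followed by the erythroid and megakaryocytic factor Nfe2 at 31.7 ± 1.42 and Tal1, a partner of GATA factors, at 28.8 ± 0.057. Gata2, the GATA factor of progenitors, stood at 18.6 ± 3.58 TPM. Klf1, an activator of adult beta-globin, reached 9.63 ± 0.141, the repressor Gfi1b 21.1 ± 2.53 and Runx1 6.08 ± 0.580. Fli1 and Spi1, ETS factors of the megakaryocytic and myeloid lineages, stood at 4.61 ± 0.566 and 4.43 ± 0.375 TPM. Sox6 was the lowest member, at 0.33 TPM in both libraries, and Meis1, chosen after its values were seen, was the other undetected member, at 0.67 ± 0.184 TPM.

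Globin RNA was unequal between the alpha and beta loci. Hba-a2 stood at 141 ± 20 TPM and Hba-a1 at 50.7 ± 8.22, whereas the adult beta-globin genes Hbb-bs and Hbb-bt stood at 2.36 ± 1.34 and 1.44 ± 0.764 TPM, both with shared-read marks. Hbb-bs went from 1.41 TPM in replicate 1 to 3.31 in replicate 2, and Hbb-bt from 0.90 to 1.98. Only 3 of the 9 measured globin genes were detected in both libraries, and embryonic Hbb-bh1 was at 0.04 ± 0.042 TPM. The list median was 0.115 ± 0.0636 TPM, at percentile 58.2.

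Haem synthesis and iron uptake were expressed except for the erythroid enzyme that starts the pathway. Of 20 genes, 19 were detected, with a median of 5.98 ± 0.0919 TPM, at percentile 99.8. The list medians within replicates 1 and 2 were 6.145 and 6.275 TPM. Ferritin light chain Ftl1 led at 781 ± 28.3 TPM, ferritin heavy chain Fth1 stood at 173 ± 18.4 and the transferrin receptor Tfrc at 106 ± 11.3. Alas2, the erythroid form of the first enzyme of haem synthesis, was the undetected member, at 0.175 ± 0.035 TPM from 61 and 39 counts, while its housekeeping counterpart Alas1 stood at 3.88 ± 0.431. Of 22 red cell membrane and late erythroid genes, 18 were detected, with a median of 5.94 ± 0.382 TPM (percentile 99.9). Carbonic anhydrase genes Car2 and Car1 led at 272 ± 4.19 and 66.8 ± 2.31 TPM, and the mitophagy receptor Bnip3l stood at 60.3 ± 6.25. Trim58 was lowest, at 0 TPM in both libraries. The other undetected members, chosen after their values were seen, were the anion exchanger Slc4a1 at 0.235 TPM, Tmod1 at 0.185 and Dmtn at 0.01.

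Receptors and signalling genes of early erythroid cells were also high, with 16 of 20 detected and a median of 10.4 ± 1.04 TPM (percentile 100). Kit, the stem cell factor receptor, stood at 88.5 ± 11.9 TPM, the survival gene Mcl1 at 47.8 ± 4.27 and the cytokine receptor subunit Csf2rb at 23.5 ± 1.08. The erythropoietin receptor Epor was at 2.74 ± 0.707 TPM. Among stem and progenitor surface markers only Kit and Cd44 (7.22 ± 0.212 TPM) of 14 were detected, and the list median was 0.0325 ± 0.0212 TPM (percentile 31.1), with Tek lowest at 0.01 and 0 TPM.

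**Figure D1:**
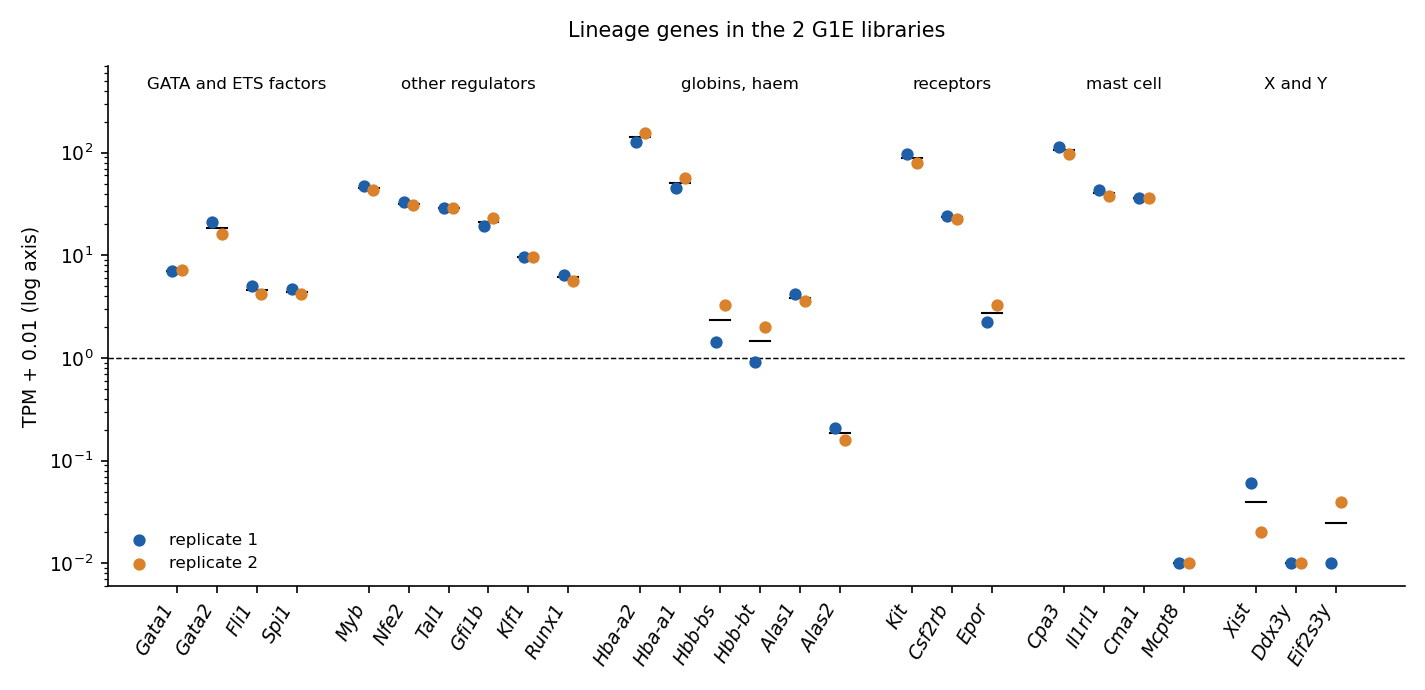
TPM + 0.01 on a log axis for named lineage genes, 1 point per library (blue, replicate 1; orange, replicate 2) with a black bar at the mean and a dashed line at a TPM of 1. Gata1 lies near 7 TPM in both libraries, alpha-globin genes lie above beta-globin genes, and Cpa3, Il1rl1 and Cma1 lie above 30 TPM while Mcpt8, Ddx3y and Eif2s3y lie near 0.

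Markers of other haematopoietic lineages were split. Of 14 mast cell and basophil markers, 8 were detected in both libraries, with a median of 2.55 ± 0.0389 TPM (percentile 92.1). Mast cell carboxypeptidase Cpa3 stood at 105 ± 11.3 TPM, the interleukin-33 receptor Il1rl1 at 40.5 ± 3.27 and the chymase Cma1 at 36.2 ± 0.212, whereas the basophil protease Mcpt8 was at 0 TPM in both libraries. Of 18 megakaryocyte markers, 6 were detected, with a median of 0.163 ± 0.0389 TPM (percentile 59.8). Plek stood at 56.3 ± 2.19 TPM, the integrin Itga2b at 13.3 ± 0.127 and platelet factor Pf4 at 5.72 ± 1.05, and Thbs1 was at 0 TPM in both libraries. Of 20 granulocyte and macrophage markers, 2 were detected, the Fc receptor Fcgr3 at 19.9 ± 2.05 TPM and lysozyme Lyz2 at 1.33 ± 0.0071; Cd68 stood at 1.13 and 0.87 TPM, S100a8 at 0, and the list median was 0.03 ± 0.0141 (percentile 26.8). None of 18 lymphoid markers was detected in both libraries at this threshold, with a median of 0.01 ± 0.0071 TPM (percentile 1.71) and Lck highest at 0.345 ± 0.049. None of 14 pluripotency and fibroblast markers was detected, with a median of 0.0175 ± 0.0035 TPM (percentile 12.4) and Col1a1 highest at 0.34 and 0 TPM.

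None of 7 Y-linked genes was detected, although the labels give the line as male. The list median was 0 TPM (percentile 0.545). Ddx3y had 0 counts in both libraries, Eif2s3y had 0 and 3, and Kdm5d had 2 in each. The highest upper bound of the authors' TPM interval among the 7 genes was 0.154. Xist, the RNA of the inactive X chromosome, stood at 0.05 and 0.01 TPM from 46 and 19 counts.

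Proliferation genes were among the highest lists. Of 24, 23 were detected, with a median of 42.3 ± 3.40 TPM (percentile 100), led by topoisomerase Top2a at 132 ± 10.3, the replication clamp Pcna at 86.0 ± 2.14 and the helicase subunit Mcm6 at 79.6 ± 3.47. Cyclin D1 (Ccnd1) was the undetected member, at 0.04 and 0 TPM. Of 15 cell cycle inhibitors and p53 targets, 12 were detected, with a median of 7.92 ± 0.898 TPM (percentile 99.8). Ccng1 stood at 49.4 ± 6.61 TPM, Gadd45a at 20.4 ± 0.212 and the p53 ligase Mdm2 at 16.3 ± 2.52, and Cdkn1c was lowest at 0 and 0.01. The undetected inhibitors Cdkn2a and Cdkn2b, chosen after their values were seen, were at 0.01 and 0.055 TPM. Of 20 subunits of nucleosome remodelling, Polycomb and co-repressor complexes, 19 were detected, with a median of 14.2 ± 0.725 TPM (percentile 99.99). The histone-binding subunit Rbbp7 stood at 105 ± 13.6 TPM, the remodelling ATPase Chd4 at 61.9 ± 7.33 and the maintenance methyltransferase Dnmt1 at 31.8 ± 5.25, while the de novo methyltransferase Dnmt3a was at 0.125 ± 0.106.

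All 17 genes of glycolysis and glucose uptake were detected, with a median of 89.3 ± 0.636 TPM (percentile 100). Gapdh stood at 524 ± 87.8 TPM, Aldoa at 398 ± 10.3 and Pkm at 364 ± 45.2, and the muscle phosphofructokinase Pfkm was lowest at 8.16 ± 1.05. Of 17 heat shock and immediate early genes, 11 were detected, with a median of 4.32 ± 0.0495 TPM (percentile 98.3). The constitutive chaperones Hspa8, Hsp90aa1 and Hspa5 stood at 597 ± 43.2, 400.0 ± 69.2 and 63.0 ± 6.77 TPM, whereas the inducible chaperone Hspa1a, with a shared-read mark, was at 0 and 0.01.

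**Figure D2:**
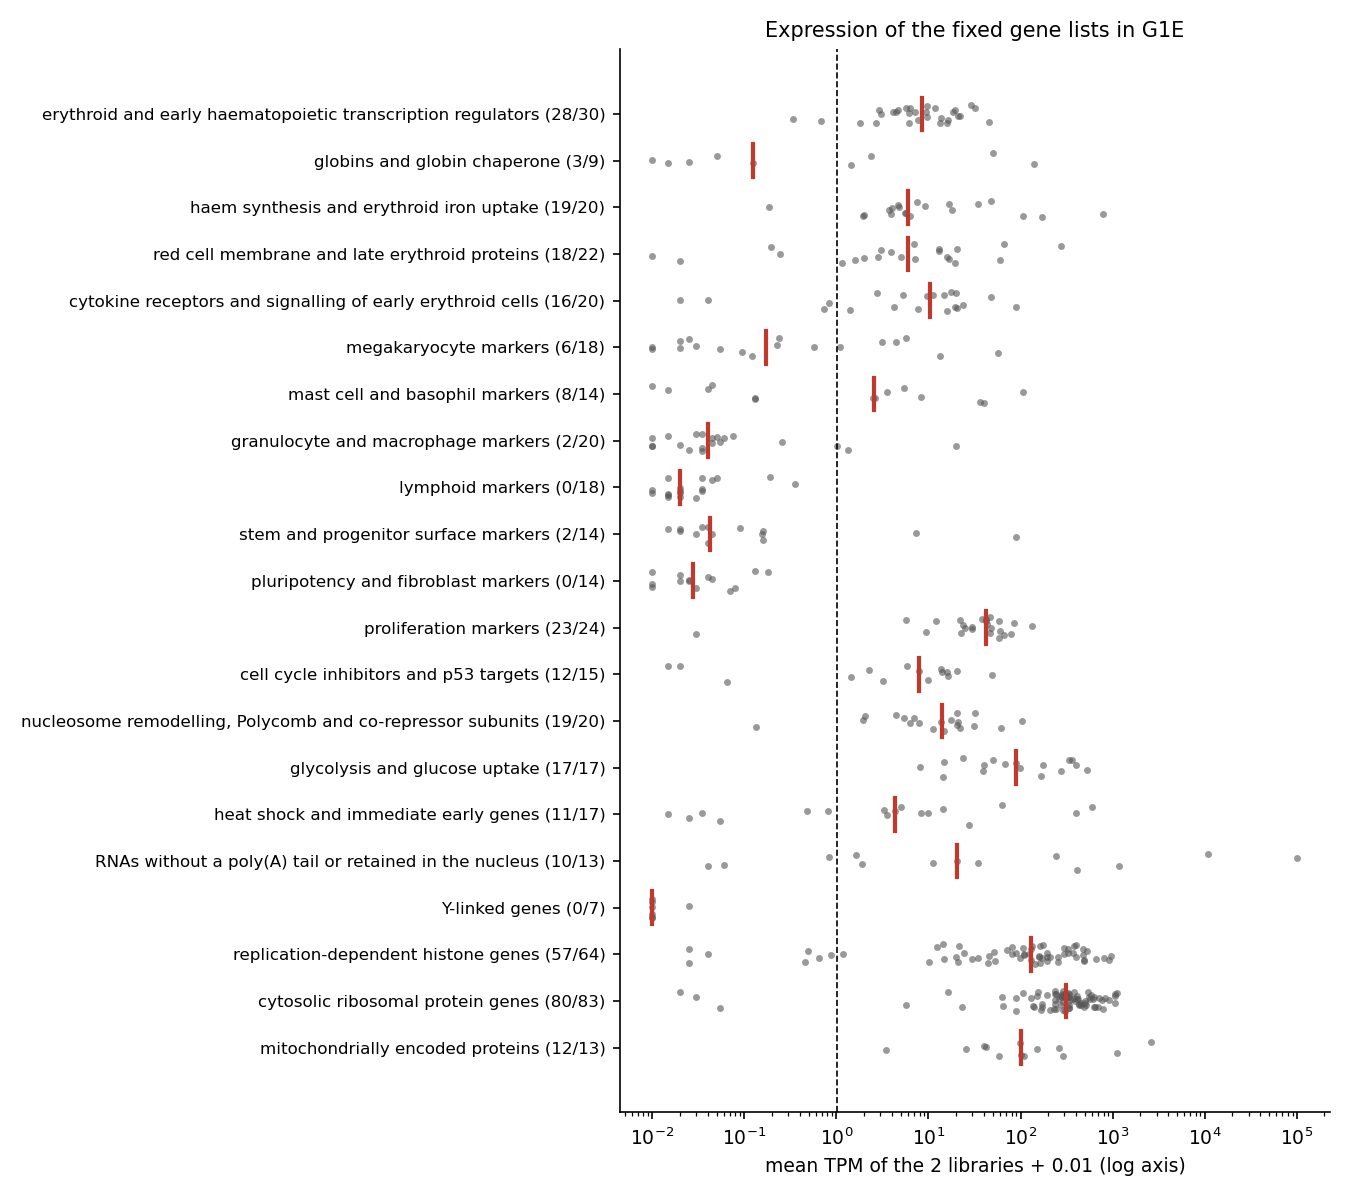
Mean TPM + 0.01 of every measured member of the 21 gene lists on a log axis, with 1 grey point per gene, a red bar at the list median and a dashed line at a TPM of 1; brackets give members detected in both libraries out of those measured. Regulators, haem synthesis, receptors, proliferation and glycolysis lie mostly above 1 TPM, and lymphoid, pluripotency and Y-linked genes lie below it.

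Of the 15 fixed pairs of related genes, 12 passed the limit, which takes the pooled SD in the bin of the lower gene. For Alas2, Hbb-bh1, Bcl2, Gfi1, Runx3 and Dnmt3a, all under 1 TPM, the SD from 1 to 10 TPM was used. Replicate error was not measured under 1 TPM, so the limits of their pairs are borrowed from higher genes. The pooled SD rose with level, so the limit is lenient where the higher gene lies in a higher bin. Stat5a lies from 10 to 100 TPM, where the limit is 1.03, and its ratio over Stat5b was 0.86 in replicate 1. Hmgb1 lies from 100 to 1000 TPM, with an SD of 0.35, whereas its limit of 1.03 used 0.24. Gata2 exceeded Gata1 by a log2 ratio of 1.26 ± 0.27, and Alas1 exceeded Alas2 by 2.05 ± 0.08. Kit exceeded Epor by 4.59 ± 0.47, Dnmt1 exceeded Dnmt3a by 4.86 ± 0.10 and Gfi1b exceeded its paralog Gfi1 by 4.35 ± 0.11. Runx1 exceeded Runx3 by 2.75 ± 0.03, the survival gene Bcl2l1 exceeded Bcl2 by 1.78 ± 0.09 and the Polycomb methyltransferase Ezh2 exceeded Ezh1 by 1.52 ± 0.04. Hmgb1 exceeded Hmgb2 by 1.28 ± 0.20, Hbb-bt exceeded Hbb-bh1 by 1.20 ± 0.40, and Stat5a exceeded Stat5b by 0.94 ± 0.11. The call of Hbb-bt is weak, as it carried a shared-read mark and stood at 0.9 and 1.98 TPM. Its partner Hbb-bh1 held 1 and 5 counts. Klf1 exceeded Fli1 by 0.93 ± 0.17 against a limit of 0.73 (log2), but with CPM and no length correction the ratio turned to -0.12. The remaining 3 pairs did not pass their limit: Spi1 against Gata1 at -0.58 ± 0.11, Tal1 against Lyl1 at 0.82 ± 0.09, and the mitochondrial iron importers Slc25a37 against Slc25a28 at -0.86 ± 0.33. In replicate 2 alone the last of these would have passed, at -1.10. Without the length correction 2 further calls were lost, Bcl2l1 against Bcl2 at 0.81 and Stat5a against Stat5b at 0.43, and Tal1 against Lyl1 passed at 2.15. With a pseudocount of 0.1 the calls of Klf1 against Fli1 and Stat5a against Stat5b were lost, at 1.05 and 1.00.

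**Figure D3:**
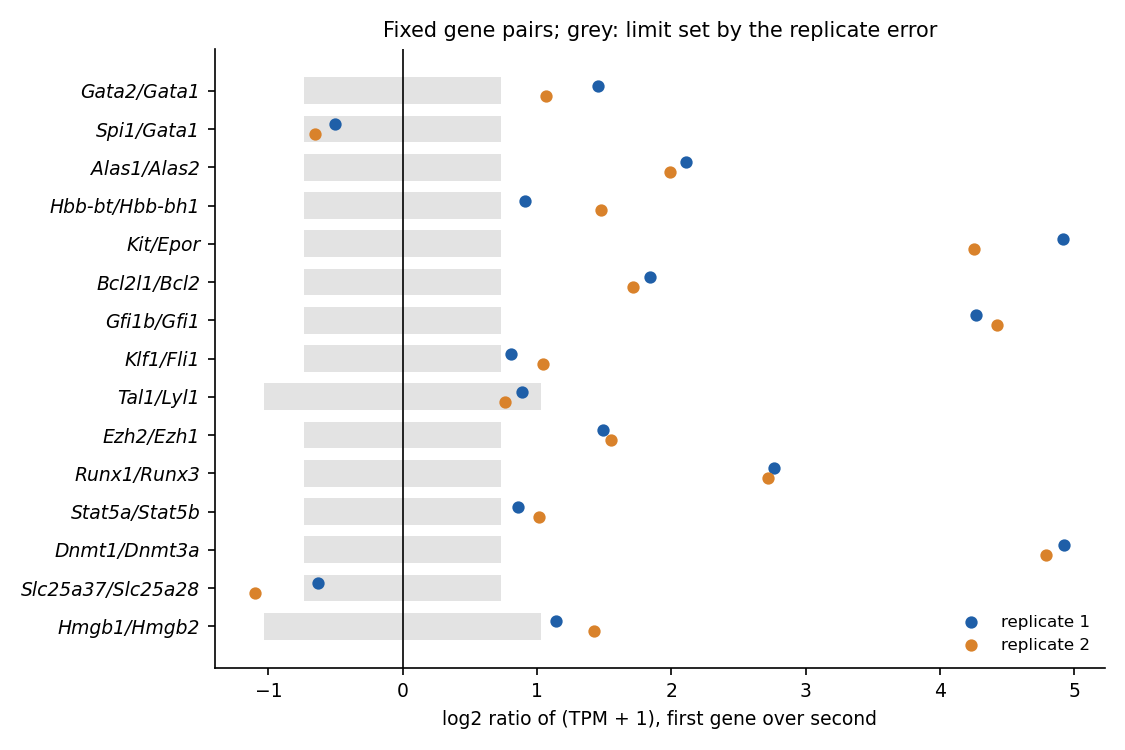
Log2 ratio of TPM + 1 of the first over the second gene for the 15 fixed pairs, 1 point per library (blue, replicate 1; orange, replicate 2). Grey bars span the limit set by the replicate error, 0.73 where the lower gene is under 10 TPM and 1.03 where it is from 10 to 100 TPM; both points lie outside the bar for 12 pairs.

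Small structured RNAs took most of the TPM although protein-coding transcripts took most of the reads. Nuclear protein-coding genes held 81.5% ± 2.08 of expected counts and 17.5% ± 0.759 of TPM. Spliceosomal and other snRNAs held 2.22% ± 0.980 of counts and 44.0% ± 0.445 of TPM, and the class with 7SK and 7SL RNA held 9.67% ± 1.34 of counts and 28.0% ± 0.478 of TPM. The 5 genes with the highest TPM were the transcription elongation regulator 7SK (Rn7sk) at 101896 ± 190.4, the signal recognition particle RNAs Rn7s2 at 88178 ± 2946 and Rn7s1 at 88131 ± 2776, and the snRNA genes Gm22513 at 54847 ± 11257 and Gm23849 at 26973 ± 5689. Rn7s2, Rn7s1 and Gm23849 carried shared-read marks. TPM divides by an effective length, which is small and uncertain for genes near or under the mean fragments of 213.2 and 192.5 nt. From replicate 1 to 2, Gm22513 rose from 95426 to 123090 counts while its TPM fell from 62807 to 46887. The TPM shares and ranks of such short RNAs are therefore uncertain. Of 13 listed RNAs without a poly(A) tail or retained in the nucleus, 10 were detected, with a median of 20.5 ± 1.99 TPM (percentile 100). The RNase MRP RNA Rmrp stood at 10789 ± 2434 TPM and the RNase P RNA Rpph1 at 1172 ± 287.

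Ribosomal protein and histone genes were among the most abundant protein-coding transcripts. Of 83 cytosolic ribosomal protein genes, 80 were detected, with a median of 316 ± 13.3 TPM (percentile 100), led by Rpl41 at 1121 ± 118, Rpl36a at 1071 ± 190, Rpl7 at 1064 ± 85.6 and Rpl32 at 1060.1 ± 3.27, with Rplp1 at 924 ± 116 and Rpl10l lowest at 0.02 and 0. Of 64 replication-dependent histone genes, 57 were detected, with a median of 131 ± 15.3 TPM (percentile 100). Hist1h4d stood at 960.0 ± 68.6 TPM, Hist1h4k at 924 ± 90.5 and Hist2h2aa1 at 807 ± 202. The germ-line variant Hist1h2ba, with a shared-read mark, was at 0 and 0.03. It tied for the lowest mean with Hist1h2aa, chosen after its values were seen, at 0.03 and 0. The other protein-coding genes with the highest TPM were the predicted gene Gm10800 at 1834 ± 443, the elongation factor Eef1a1 at 1600 ± 17.4 and the metallothionein Mt1 at 942 ± 83.8. Of 13 mitochondrially encoded protein genes, 12 were detected, with a median of 101 ± 45.9 TPM (percentile 100). mt-Co1 stood at 2637 ± 735 TPM and mt-Atp8 at 1126 ± 167, whereas mt-Co3 stood at 290.1 ± 117 with a shared-read mark. mt-Nd4l, also with that mark, was at 6.97 TPM in replicate 1 and 0 in replicate 2.

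Across all genes, 9113 of 43346 were detected in both libraries, 8303 of them among the 21461 nuclear protein-coding genes (38.7%). Replicate 1 alone gave 9385 and replicate 2 alone 9420, and 579 genes reached the threshold in 1 library only. After rescaling, 9574 protein-coding genes reached it in both. A threshold of 5 TPM lowered the 9113 genes to 5332.

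Most named genes were carried by the same transcript in both libraries. Of 58 named genes with at least 2 transcripts, 50 had the same leading transcript, and the median share of the leader was 76.9% of the gene's TPM. For Gata1 the leader, a coding transcript of 1902 nt, held 91.5% ± 0.03 of Gata1 TPM. For Gata2 the leader differed between libraries, as its transcript of 3133 nt held 57.6% in replicate 1 and 47.8% in replicate 2. A Kit transcript of 5214 nt held 55.2% ± 0.95 of its gene, and a Tal1 transcript of 4213 nt held 96.3% ± 2.18. A transcript of Hbb-bs with a retained intron (549 nt) held 44.0% of Hbb-bs in replicate 1 and 77.1% in replicate 2. Over the 58 genes the libraries differed by a median of 3.58 percentage points.

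The pooled SD of log2 TPM was 0.21 over detected genes, a factor of 1.16, and 0.17 over nuclear protein-coding genes. It was 0.17 from 1 to 10 TPM, 0.24 from 10 to 100, 0.35 from 100 to 1000 and 0.49 above 1000. The pseudocount of 1 shrinks differences most in the lowest bin, and the median difference between the libraries was not removed. Pearson's r was 0.987 and Spearman's rho 0.982 across detected genes, which are not independent replicates. The biological coefficient of variation was 16.1% with edgeR. It was 30.8% with no filter on low counts. TPM in replicate 2 was lower by a median log2 of -0.11, and list shifts in TPM are given relative to that.

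Beyond counting error the libraries differed by class of RNA and by level. Of 112 snoRNA genes tested, 86 were higher and 2 lower in replicate 2 at 2-fold or more, with a median log2 count difference of 1.97. Of 53 snRNA genes, 33 were higher and 2 lower, with a median of 1.26, and of 17 scaRNA genes, 9 were higher and none lower, with a median of 1.36. In TPM relative to the median gene, which includes the authors' length correction, the median was 0.51 for 41 snRNA genes. For 110 snoRNA and scaRNA genes it was 0.86, and neither value uses a pseudocount. The snRNA class held 43.7% and 44.3% of TPM in replicates 1 and 2. Protein-coding genes at low counts went the other way. Of 4316 with a mean of 5 to 50 counts, 1107 were lower and 248 higher in replicate 2, with a median log2 of -0.61, whereas of 5635 with a mean of 1000 to 10000 counts, 1 was lower and 8 higher, with a median of 0.01. Over all types, 2561 of 18409 tested genes (13.9%) passed the exact binomial test and 2-fold, 711 higher and 1850 lower in replicate 2; among protein-coding genes, 310 were higher and 1137 lower out of 14092 tested. With at least 100 counts over both libraries the number was 254 and the balance turned, with 178 higher and 76 lower, and with no minimum fold it was 8993. The chi-square of the counts was 62.8 per degree of freedom over 18408, so the deposited libraries were not 1 library in duplicate.

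Most protein-coding genes with the largest differences carried the shared-read mark. The 5 furthest up in replicate 2 were Hist2h3c1, from 0 to 265 counts, Nanp, from 0 to 128, Gm14308, from 33.5 to 481, Prss36, from 16 to 104, and Gm14419, from 154 to 709. The 5 furthest down were mt-Nd4l, from 110 counts to 0, Gm3055, from 102 to 0, Gm2004, from 818 to 13.1, Hist1h4m, from 555 to 116, and Gm14288, from 869 to 191. For Gm2004 the TPM was 3.23 and 2.57, so its count difference came with a change in the length assigned to it. All but the serine protease gene Prss36 carried the shared-read mark. For Prss36 the log2 difference in counts was 2.79, but the authors' TPM intervals, 0.131 to 1.558 in replicate 1 and 0.766 to 1.813 in replicate 2, overlap.

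Of 20 gene lists with at least 3 tested members, 7 shifted between libraries further than random lists of like expression. Each shift below is the median log2 difference in counts, followed by that in TPM relative to the median gene. Replication-dependent histone genes were higher in replicate 2 by 0.45 (TPM 0.32; percentile 100; 61 members), ribosomal protein genes by 0.22 (TPM 0.12; percentile 100; 80 members) and globins by 0.51 (TPM 0.44; percentile 99.2; 5 members). Granulocyte and macrophage markers shifted by 0.38 (TPM 0.14, percentile 98.2, 11 members, most of them under 1 TPM), although 1 member was called higher and 2 lower. The pseudocount of 1 holds TPM differences near 0 for such low genes, so most of the 0.14 comes from subtracting the median gene's -0.11. Proliferation genes shifted by 0.08 (percentile 99.0) with 14 members higher and 10 lower, the only called member being lower, and in TPM by 0.02 (percentile 95.9), inside the middle 95%. Mitochondrially encoded proteins were lower, at -0.29 (TPM -0.39, percentile 0), with 10 members lower and 3 higher. Of these, mt-Co3 was called higher and mt-Nd4l lower, both with shared-read marks. Remodelling and Polycomb subunits were lower too, at -0.14 (TPM -0.14, percentile 0.37), with no member called. Among random lists matched on gene length as well, a comparison chosen after seeing the data, ribosomal proteins moved to percentile 94.4 and globins to 97.0, inside the middle 95%. The other 13 lists lay inside the middle 95%, among them haem synthesis at 0.09 (TPM 0.04; percentile 92.6) and mast cell markers at 0.09 (TPM 0.09; percentile 84.4). Lymphoid markers, with 3 members higher and 4 lower, were at -1.37 in counts (percentile 7.34) and 0.08 in TPM (percentile 46.1). All of them lay under 1 TPM, so the 0.08 comes from the same subtraction and its sign gives no direction.

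**Figure D4:**
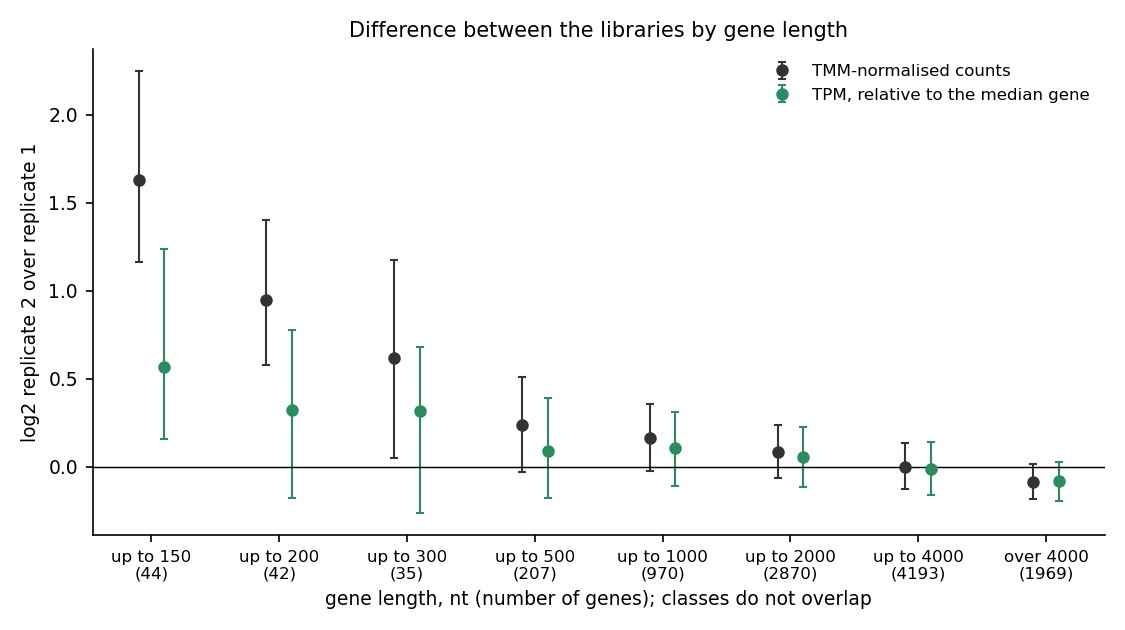
Median log2 difference of replicate 2 over replicate 1 by gene length in nt, for genes with at least 200 counts over both libraries; bars span the interquartile range, black for TMM-normalised counts and green for TPM relative to the median gene. In counts the median falls from 1.63 in genes of up to 150 nt to -0.09 in genes over 4000 nt. In TPM, taken without a pseudocount, it falls from 0.57 to -0.08.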

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

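The tests of explanations below were all chosen after the results they bear on had been seen, and no biological explanation between groups was tested, since the design has 1 group.

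Rows of the gene tables with numeric names, which no comparison uses, held 20 expected counts in replicate 1 over 7 such rows and 37.61 in replicate 2 over 15. There were no control samples to set them against.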

How the results depend on the processing

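Alternatives were fixed before the data were examined, except random lists matched on length, chosen after the result was seen. Genes detected in both libraries, 9113 as reported, became 5332 at 5 TPM and lay between 10061 and 13323 under the other thresholds and units, and between 9385 and 9420 with either replicate left out. The pooled SD, 0.212 as reported, was 0.241 with a pseudocount of 0.1, 0.226 with 0.5, 0.253 with no filter, 0.242 at 10 TPM or more, 0.278 with posterior mean TPM and 0.249 with rescaled TPM. The coefficient of variation, 16.1% as reported, was 30.8% with no filter, 13.4% at 100 counts or more and 13.01% as the median fitted dispersion of DESeq2, and stayed at 16.0% with DESeq2 size factors or library totals. Genes past counting error and 2-fold, 2561 as reported, fell to 254 at 100 counts or more, were 8993 with no minimum fold and 1650 at 4-fold, and lay between 2496 and 2800 otherwise. The higher share in replicate 2, 27.8% as reported, was 70.1% at 100 counts or more and 45.9% with no minimum fold. Gata1 stood at 40.6 TPM after rescaling, a change of denominator, and between 7.06 and 7.13 TPM with either replicate left out. The median leading transcript share was 85.7% by counts and 77.1% with either replicate left out. Lists shifted between libraries numbered 7 as reported and with DESeq2 size factors, 6 in TPM and 5 when matched on length; of 60 list shifts under an alternative, 3 lost their call. List genes detected lay between 287 and 357 (340 as reported), and 342 and 343 without a replicate. Pairs past the replicate spread numbered 12 as reported, 10 with a pseudocount of 0.1 (Klf1 against Fli1 at 1.05 and Stat5a against Stat5b at 1.00 no longer passed) or without length correction, and 12 and 13 without a replicate. Klf1 against Fli1 turned from 0.93 to -0.12 without length correction, as Klf1 has the shorter transcript. Of 90 pair values under an alternative, 83 kept their side, 4 lost and 2 gained a call. No paired analysis was possible because the design has 1 group.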

Other observations

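The gene groups in this and the next paragraph were chosen after their values were seen, as were the explanation tests that follow. Among 39 Hox genes, 4 were detected in both libraries: Hoxb13 at 7.63 ± 0.622 TPM, and the neighbours Hoxc4, Hoxc6 and Hoxc5 at 2.09 ± 0.240, 1.87 ± 0.516 and 1.5 ± 0.262 TPM (SD, n = 2). Hoxb13 is the outermost gene of its cluster, and its nearest Hox neighbour, Hoxb9, was at 0 and 0.01 TPM. Of 7 RNA-binding and chromatin proteins known from fetal cells, 4 were detected: Hmga1 stood at 19.4 ± 0.728, Igf2bp1 at 7.92 ± 1.77, Igf2bp3 at 6.47 ± 1.11 and Lin28b at 2.56 ± 0.170 TPM, whereas Igf2bp2 was at 0.115 ± 0.064, Hmga2 at 0.035 ± 0.035 and Lin28a at 0.015 ± 0.007. Of 15 imprinted genes, 4 were detected, Igf2r at 13.4 ± 0.905, Snrpn at 5.48 ± 0.495, Impact at 4.19 ± 0.559 and Peg3 at 4.10 ± 0.665 TPM, while H19 and Igf2 were at 0.02 and 0.035.

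Of 18 sterol synthesis and uptake genes, 17 were detected, with a median of 11.8 TPM that was not set against random lists. Idi1 stood at 163 ± 15.4 and Msmo1 at 101 ± 6.96 TPM, and Insig1, a retention factor of the same pathway, was the undetected member at 0.305 ± 0.007. Of 13 genes of the amino acid stress response, 8 were detected, with a median of 1.54 TPM: asparagine synthetase Asns was highest at 109 ± 9.23 TPM, while Trib3 was at 0.365, Slc7a11 at 0.17 and Chac1 at 0. Within serine synthesis, Psat1 was at 25.1 ± 2.25 TPM and Phgdh, the enzyme before it, at 0 and 0.02. Of 10 telomerase and telomere genes, 9 were detected. The template RNA Terc stood at 34.3 ± 7.59 TPM and the telomerase protein gene Tert at 0 and 0.01, in a line described as immortalized. Of 4 metallothionein genes, 2 were detected, and Mt2 stood at 378 ± 91.4 TPM beside Mt1 at 942 ± 83.8.

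Gata1 RNA was present at 7.06 and 7.13 TPM in the line labelled Gata1-. Reads shared with other GATA genes are argued against by the posterior SD of the Gata1 count, 0.0% of the count at most. Beta-globin and Alas2 RNA, which maturing GATA1-positive erythroid cells in the culture would bring in abundance, argue against such cells as a source. Hbb-bs and Hbb-bt together stood at 0.327 and 0.742 times Gata1 TPM, and Alas2 at 0.028 and 0.021 times. Alpha-globin went the other way, with Hba-a2 at 126.4 and 154.7 TPM and Hba-a1 at 44.9 and 56.5, so the globin genes alone do not decide it. Transcription of the altered allele may account for the RNA but cannot be told apart from an intact one, because gene and transcript totals (a coding transcript of 1902 nt held 91.5% of the TPM) do not show which exons the reads cover.

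Y-linked genes were near 0 counts in both libraries of a line labelled male. Too little depth is argued against, since the lowest of 6 X-linked homologues (Ddx3x, Eif2s3x, Kdm5c, Kdm6a, Zfx and Usp9x, chosen after their values were seen) still held 5451 counts. Assignment of Y-linked reads to those homologues is argued against by the authors' intervals, whose highest upper bound over the 7 Y-linked genes was 0.154 TPM. Cells without a Y chromosome are a candidate explanation: 0 of 183 protein-coding genes annotated on the Y chromosome reached 1 TPM in both libraries, and together they held 11 and 9 counts. A gene that such cells do not express stays near 0 with or without the chromosome. How many of the 183 they would express was not examined, so that number can overstate the support. Loss of the chromosome in culture and a line that never had it cannot be told apart by RNA totals, which also do not say whether the label describes the donor or the cells, and Xist gave 46 and 19 counts.

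Short RNAs held more counts in replicate 2, whose mean fragment was shorter, at 192.5 nt against 213.2 nt by the files' effective lengths. Genes up to 300 nt and over 2000 nt differed by a median log2 of 1.16 and -0.03, 1.19 apart, a gap that 1 scaling factor per library leaves unchanged by definition. Shorter fragments in replicate 2 may account for part of it: the authors' effective length correction lowered the median log2 difference from 1.14 to 0.51 for 41 snRNA genes and from 1.77 to 0.86 for 110 snoRNA and scaRNA genes. Whether the rest is fragment length or another difference between the preparations cannot be told apart, as that correction is least certain near the fragment length. For 61 histone genes fragment length as the whole cause is argued against by random lists matched on expression and gene length. Their median count difference of 0.45 lay at percentile 100 of those lists. After the correction their median stayed at 0.32, at percentile 100 of lists matched on expression alone, which do not test length. The 0.32 uses a pseudocount of 1, unlike the corrected values of the snRNA, snoRNA and scaRNA genes.

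Protein-coding genes with a mean of 5 to 50 counts were lower in replicate 2 by a median log2 of -0.61, against 0.08 for those with 100 to 1000 counts. mt-Co1 held 2637 ± 735 TPM, against a median of 101 ± 45.9 for the 13 mitochondrially encoded protein genes. The mast cell genes Cpa3 and Cma1 stood at 105 ± 11.3 and 36.2 ± 0.212 TPM. The Fc receptor subunits Fcer1g and Fcer1a, chosen after their values were seen, stood at 0.12 and 0.03. Ms4a2, the gene of a further subunit of that receptor and chosen in the same way, was detected at 3.56 ± 0.028 TPM.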
